A study of Homo sapiens with 15 samples.

How the data were processed

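Chromatin accessibility was measured by InTAC-seq in 15 libraries of sorted developing B cells from the bone marrow of 2 donors. Per the labels' protocols, cells were depleted of other lineages, stained for surface markers, fixed, permeabilised, stained for TdT and sorted, and 50K cells went into each replicate. Per the submitters' processing notes, bcl2fastq, FastQC, Bowtie2, Picard and MACS2 were used; their versions, settings, filters and thresholds are not given in the sources used here. The deposited files are lists of peak summits, 1 list per library, so that replicates were not pooled. Each line gives a 1-bp position and a score. The score deposited by the authors is the −log10 of the summit's q-value or p-value in its own library; which of the 2 is not given in the sources used here. It grows with depth and signal over background, so it was used only to rank and filter summits within a list. Reads per library were not used here, and the depth is unknown.

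The submitters' processing notes name both hg38 and hg19. The coordinates were taken as hg19, because 851 summits on chromosome 1 lie past the end of that chromosome in hg38. No genome sequence or gene annotation of hg19 was used here, and no coordinate was converted. Positions are located by the 811 autosomal cytogenetic bands of hg19, from the UCSC table carried by an R package. Genes are placed in bands from textbook knowledge, as background, and no summit was assigned to a gene.

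The design fixed before the data were examined counted summits per gene, and tested gene lists and sequence motifs. Without a matching annotation and genome these could not be run. The same test was applied to windows of 100 kb, a unit chosen after the build of the coordinates was known, and the gene lists, the motif tests and the gene-based ranking of S4 were left out. The band of 1 gene of the fixed design is not reported here. Autosomes alone were used. From each library the 100000 summits with the highest score were taken. Overlap of 2 lists is the share of summits with a summit of the other list within 100 bp, as the mean of both directions. No library pair shared more than 81.9% of its summits, so none was treated as a duplicate.

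The technical replicates of a donor and population were averaged, which left 7 units: 2 donors each for LSP, S1 and S2 and 1 for S4. Windows with a mean of at least 2 summits were tested with limma 3.58.1 (R 4.3.3) on log2(summits + 1), with a trended prior and Benjamini-Hochberg adjusted p under 0.05. All 4 populations shared 1 estimate of the spread, with 3 residual degrees of freedom. The fit without a block was chosen as the main one before the data were examined. The labels number the biological replicates of each population 1 and 2 and speak of 2 separate donors. The numbers were read as the donors, which the labels do not state, and on that reading they pair the samples. The deviations from the population means correlated across windows at 0.62 for LSP and S1, 0.52 for LSP and S2 and 0.60 for S1 and S2. The blocked value is therefore printed where it moves a count by more than 1.5 times. Up to 12 windows per direction were named, the largest log2 differences among those past the threshold with the same sign in both donors, along with windows in the bands of genes fixed beforehand. Rules chosen after the data were seen named windows from the blocked fit (6 per direction), windows of S4 (the largest differences within donor 2) and regions (the 5 with the best mean rank per direction and no summit of the other population within 1000 bp). On simulated data with 12837 windows, the test recovered 91% of 4-fold changes for LSP against S1 and for LSP against S2. It recovered 17% and 18% of 2-fold changes, with 4 and 2 false calls. The simulated counts varied around a common mean per window, with a small independent spread between units. No donor effect shared by populations and no weak S1 unit was simulated, so these rates may not hold for the real libraries.

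Consensus regions were built by taking summits in order of rank; a summit within 100 bp of a region's centre joined it. This gave 331911 regions, of which 20126 were found in all 15 libraries and 125635 in 1 library. A region was specific to a population if all 4 of its libraries (technical replicates 1 and 2 of both donors) held it and none of the other population's did. With 2 donors no regrouping test of a single region can pass a threshold. The counts are set beside those of the other 2 groupings of the 4 donor units, by donor and with donors crossed. Region building was tested on simulated lists. The alternatives were lists of 50000 summits, all deposited summits, a score of at least 10, tolerances of 50 and 250 bp, windows of 50 kb, a pseudocount of 0.5, no filter, the donor as a block, libraries with an estimated correlation, no S4, and each donor unit left out. Alternatives added after the data were seen were S1 without donor 2, and regions with no summit of the other population within 1000 bp at any rank. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.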

Results

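Open chromatin was profiled in sorted populations of developing B cells from human bone marrow. The assay, InTAC-seq, is a form of ATAC-seq: the Tn5 transposase cuts accessible DNA in cells that were fixed, permeabilised, stained for an intracellular protein and sorted, so that intracellular markers such as TdT can be used for gating. The labels name 4 populations, LSP, S1, S2 and S4, without spelling the names out, and place them at switch points of the epigenome during B-cell development. LSP had 5 libraries (3 technical replicates of donor 1 and 2 of donor 2). S1 and S2 had 4 libraries each, 2 per donor, and S4 had 2 libraries from donor 2. Each of the 15 libraries came as its own list of peak summits, with 185256 to 431075 summits. Read depth is unknown, and the number of summits is set by depth, background and calling threshold together. Equal lists of the 100000 best-scoring autosomal summits of each library were therefore compared. The score is the authors' own value per peak, and it fell to between 4.68 and 17.7 at the end of these lists. The S1 libraries of donor 2 stood apart from the rest. They held 35555 and 35580 summits with a score of at least 10, against 72623 to 137175 in the other libraries, and 49.4% and 50.2% of their equal lists lay in Giemsa-negative (gene-rich) bands, against 56.8% to 62.0% elsewhere.

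The first question was whether the lists followed the populations. Summits within 100 bp of each other were counted as shared. LSP lists of the 2 donors shared 71.3% of their summits and S2 lists shared 71.1%, whereas LSP and S2 lists of the same donor shared 56.2% in donor 1 and 50.6% in donor 2. S1 did not follow this order. S1 lists of the 2 donors shared 51.2%, while S1 of donor 1 shared 65.8% with LSP and 64.5% with S2 of its own donor, and 57.6% and 59.6% with those of donor 2. S1 of donor 2 shared 46.4% with LSP and 46.0% with S2 of its own donor. In donor 2, S4 shared 62.4% with S2, 54.0% with LSP and 44% with S1. Technical replicates shared 72.9% ± 12.5 (SD, n = 7 pairs of donor and population), a mean lowered by the S1 libraries of donor 2 at 45.4%, and 77.5% ± 3.07 (SD, n = 6) without them. Donors of one population shared 64.5% ± 11.6 (SD, n = 3), and different populations shared 54.4% ± 8.35 (SD, n = 9) within a donor and 53.9% ± 6.04 (SD, n = 9) across donors. Across donors, LSP, S1 and S2 lists of the same population shared 12.8 percentage points more than lists of different populations (one-sided exact permutation test over 6 pairings, p = 0.167, the smallest p this design allows).

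**Figure D1:**
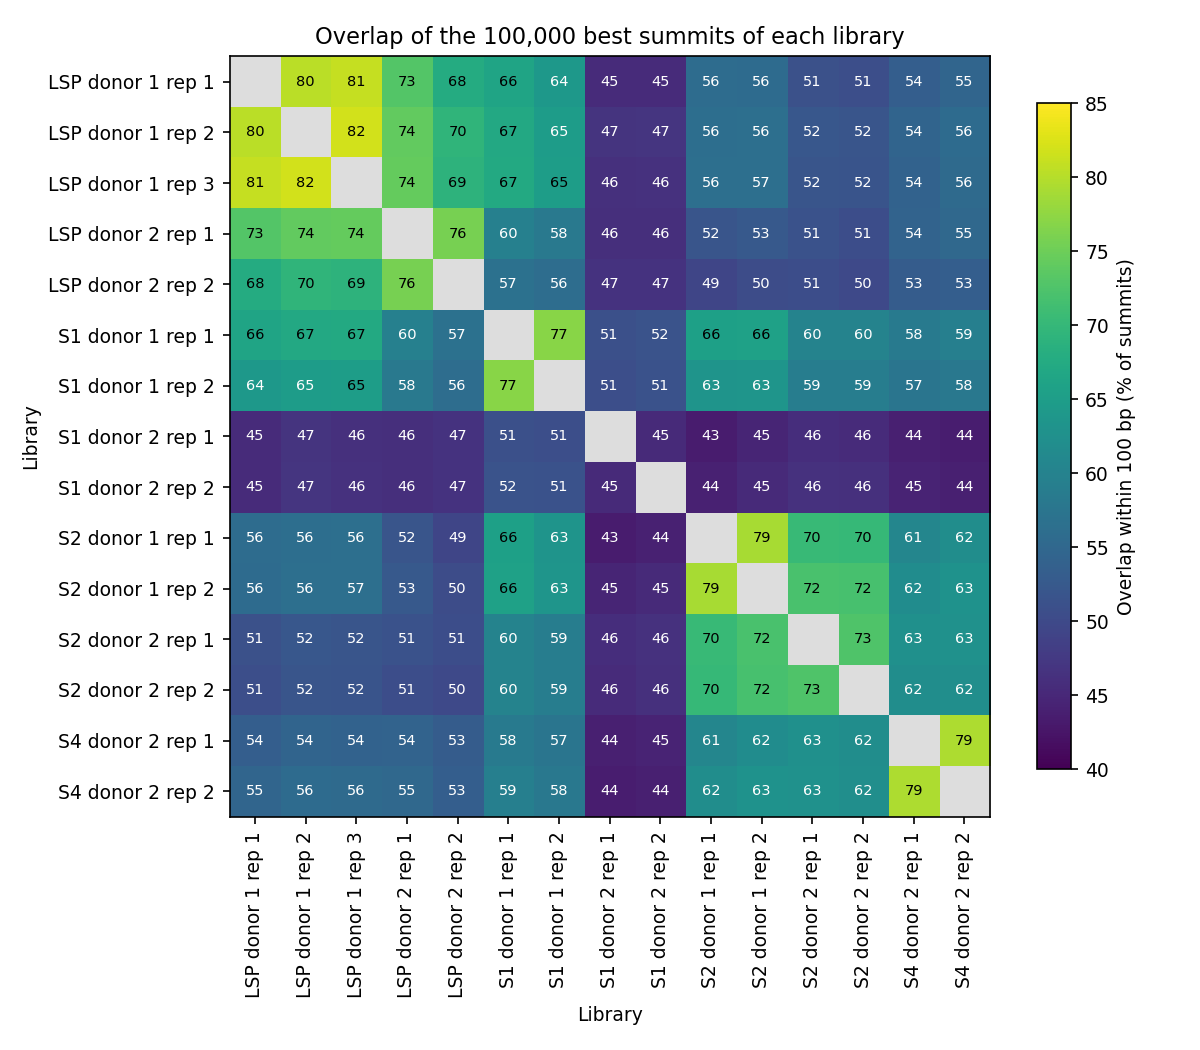
Percent of summits shared within 100 bp between the equal lists of each pair of the 15 libraries, as the mean of both directions, with libraries on both axes and technical replicates written as rep. The LSP libraries and the S2 libraries form blocks that span both donors, and the S1 libraries of donor 2 share 45.4% of their summits with each other.

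LSP and S2 differed at several bands that carry genes of B-cell identity and antigen receptor assembly. These bands were chosen for their genes, and some bands elsewhere held more called windows, as given below. Windows of 100 kb stand in for genes here, and no summit was assigned to a gene, so genes are named only as residents of a band. In 5q33.3, the band of EBF1 (a transcription factor needed to start the B-cell programme), the window on chromosome 5 from 158200001 to 158300000 held 1.5 ± 0.71 summits in LSP and 23 ± 1.41 in S2 (SD, n = 2 donors). In 9p13.2, the band of PAX5 (the factor of B-cell commitment), the window on chromosome 9 from 37300001 to 37400000 held 1.08 ± 0.82 in LSP and 13.25 ± 1.06 in S2. In 11p12, the band of RAG1 and RAG2 (the recombinase that joins antigen receptor segments), the window on chromosome 11 from 36600001 to 36700000 held 6.83 ± 0.24 in LSP and 19 ± 1.41 in S2.

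Of 12828 windows tested with limma, 489 differed between LSP and S2 at a Benjamini-Hochberg adjusted p under 0.05, 218 with more summits in LSP and 271 with more in S2. Among the windows higher in S2, 6 of the 32 tested in 5q33.3 were called, as were 3 of 19 in 9p13.2 and both called windows of 11p12, of 7 tested there. The immunoglobulin bands also held called windows higher in S2. They were 5 of 42 in 2p11.2 (the band of the kappa light chain locus IGK), where 1 more was higher in LSP, and 3 of 26 in 14q32.33 (the band of the heavy chain locus IGH). The strongest in 2p11.2 lay on chromosome 2 in the 100 kb from 89400001, with 0.67 ± 0.47 summits in LSP and 13.25 ± 1.06 in S2 (log2 difference LSP minus S2 of -3.12, SE 0.29, adjusted p = 0.0259). In 14q32.33 the window on chromosome 14 from 106700001 to 106800000 held 3.42 ± 1.30 in LSP and 21.25 ± 3.89 in S2 (log2 difference of -2.35, SE 0.35, adjusted p = 0.0361). In 10q24.1, the band of DNTT (which encodes TdT), 1 of 21 windows was called and it was higher in LSP, with 8.50 ± 0.71 summits against 2.00 ± 0.71 (adjusted p = 0.0410, and 0.0533 and 0.0529 without the S1 unit of donor 1 or donor 2). That window lay on chromosome 10 from 97500001 to 97600000 and was not assigned to DNTT. The whole of 10q24.1 held 1.006 ± 0.002 times as many summits in S2 as in LSP (SD, n = 2 donors). The bands of CD34 (1q32.2), MS4A1 (11q12.2), IGLL1 (22q11.23), and VPREB1 with the lambda locus IGL (22q11.22) held 0 called windows among 24, 16, 17 and 12 tested.

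Outside these bands, the windows with the largest differences mostly held summits in only 1 of the 2 populations. Fold changes are on the log2(summits + 1) scale and understate changes from low counts. The largest gain in S2 lay in 7q11.22, on chromosome 7 from 69800001 to 69900000, with 0 summits in LSP and 10.5 in S2 in both donors (log2 difference of -3.52, SE 0.29, adjusted p = 0.0259). Then came 6q21 (chromosome 6 from 107100001, -3.52), 3p24.2 (chromosome 3 from 26100001, -3.42), 20p11.21 (chromosome 20 from 24700001, -3.37), 5q11.2 (chromosome 5 from 54200001, -3.36) and 5q31.1 (chromosome 5 from 133100001, -3.35). In 4q31.3 the neighbouring windows that start at 152900001 and 153000001 on chromosome 4 gave -3.18 and -3.11, and the window in 3p14.2 that starts at 60200001 on chromosome 3 gave -3.17. By number of called windows higher in S2, 2p25.3 held 7 of 28 tested, and 7q11.22 and 5p15.33 held 5 each, of 15 and 24 tested.

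In the other direction, the largest excess in LSP lay in 1q44, on chromosome 1 from 247600001 to 247700000, with 10.3 ± 0.94 summits in LSP and 0 in every S2 library (log2 difference of 3.50, SE 0.32, adjusted p = 0.0259). It was followed by 17p12 (chromosome 17 from 15100001, 3.34), 9q32 (chromosome 9 from 115600001, 3.25), 11q23.1 (chromosome 11 from 110800001, 3.17), 10q23.33 (chromosome 10 from 95300001, 3.15) and 5q11.2 (chromosome 5 from 55400001, 3.11). The window in 9q21.13 that starts at 75000001 gave 3.09, and those in 20q12, 15q14, 9q34.2, 3p25.2 and 13q14.2 gave 3.07, 3.06, 3.06, 2.99 and 2.98. The bands 9q21.33 and 6q25.1 held 4 called windows each that were higher in LSP, of 13 and 28 tested, and 6q25.1 also held 2 higher in S2.

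With the donor as a block, 2169 windows passed between LSP and S2 (1106 higher in LSP and 1063 higher in S2), and all 489 were among them. Fits that left out either LSP donor or either S2 donor were made without a block. They have 1 unit of that population and 2 residual degrees of freedom. The calls did not hold in them, and their counts are given further below. In these fits the window in 1q44 gave 3.42 to 3.59 and that in 7q11.22 gave -3.52. Both were chosen for a large difference of the same sign in both donors, so their kept size is no separate support. Other named windows differed more between donors 1 and 2, with -2.83 and -3.91 in 20p11.21 and 2.83 and 3.86 in 17p12. With all donor units and no block, the count of called windows was 0 with a score minimum of 10 and 0 without the filter on low windows. In limma, 829 and 4036 windows then had an unadjusted p under 0.05.

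**Figure D2:**
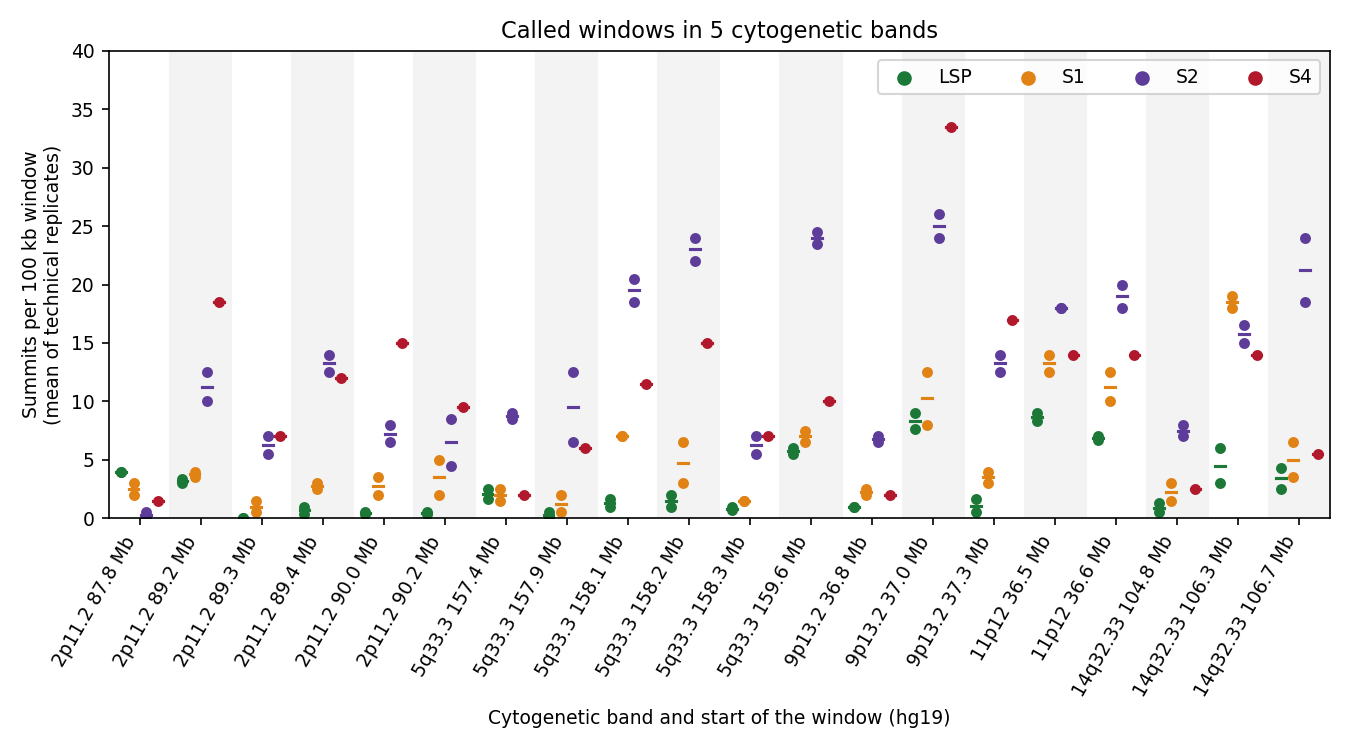
Summits per 100 kb window (vertical axis) in the windows called between LSP and S2 in bands 2p11.2, 5q33.3, 9p13.2, 11p12 and 14q32.33, each named by its band and start in hg19 (horizontal axis). Points are donors, as means of their technical replicates, and short bars are population means; S4 has 1 donor. In the window of 5q33.3 that starts at 158200001, S2 holds 23 summits and LSP 1.5.

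**Figure D3:**
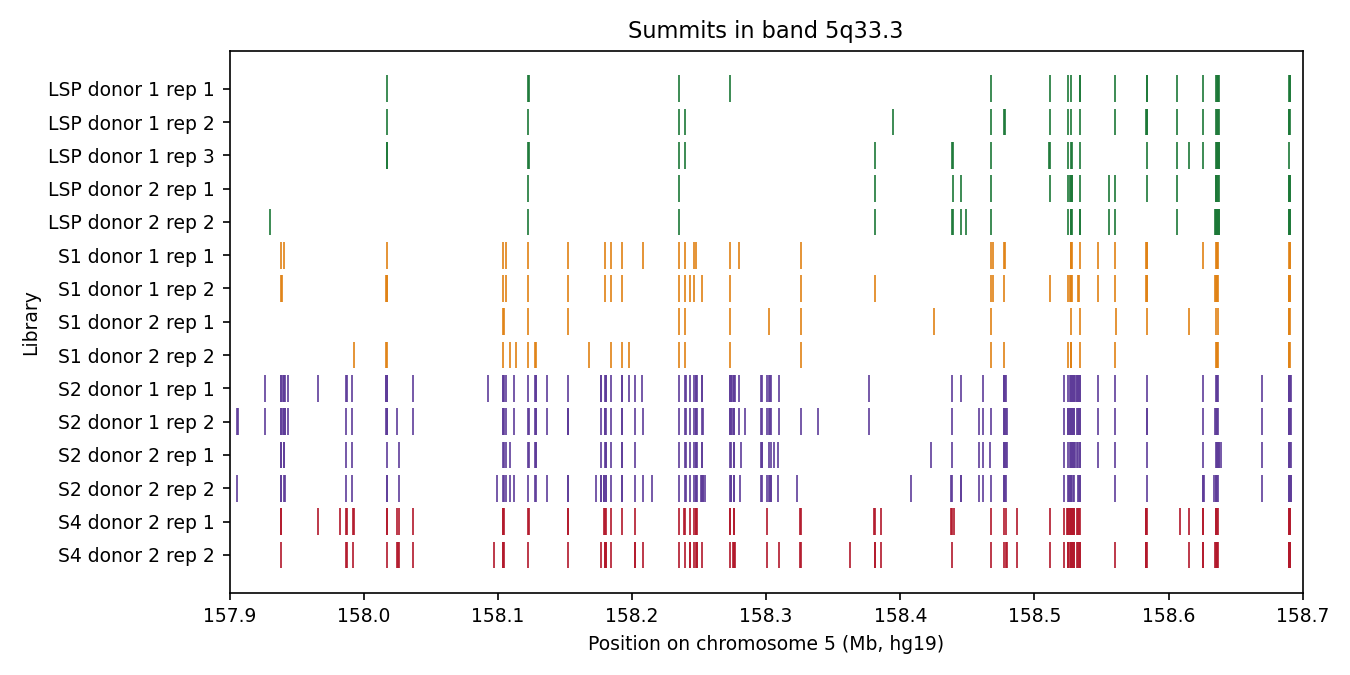
Summits of the equal lists in a stretch of band 5q33.3 on chromosome 5 (hg19) around the windows that start at 158100001 and 158200001, with position in Mb on the horizontal axis and 1 row of ticks per library. The S2 libraries hold 89 to 119 summits in this span and the LSP libraries 24 to 30.

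At single regions, LSP and S2 were told apart in many places. There were 12850 regions found in all 4 LSP libraries used and in no S2 library, and 12023 of the reverse kind. Crossing the donors between the populations gave 76 and 87 regions, and grouping by donor gave 775 and 438. In 5q33.3, 94 regions were specific to S2 and 30 to LSP; the values were 79 and 17 in 14q32.33, 38 and 8 in 9p13.2, 31 and 7 in 22q11.22, and 20 and 3 in 11p12. Specific here means absent from the other population's equal lists, and the other population often had a weaker or displaced summit. A summit of S2 lay within 100 bp at some rank for 48.2% of the LSP-specific regions, and a summit of LSP for 49.5% of the S2-specific regions. Among the 100 best-ranked regions of each kind, 76 and 54 had a summit of the other population within 500 bp in its equal lists. A criterion chosen after the data were seen required no summit of the other population within 1000 bp at any rank. It left 0 and 0 regions for crossed donors and 13 and 10 for grouping by donor. For grouping by population it left 3293 LSP-specific and 2923 S2-specific regions. The best-ranked of these in LSP lay at position 26231986 of chromosome 2 (2p23.3), 33833404 of chromosome 3 (3p22.3) and 11324008 of chromosome 6 (6p24.2). The best-ranked in S2 lay at 108088036 of chromosome 1 (1p13.3), 83120013 of chromosome 6 (6q14.1) and 107150493 of chromosome 6 (6q21), and 157621720 of chromosome 5 (5q33.3) was the fifth.

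**Figure D4:**
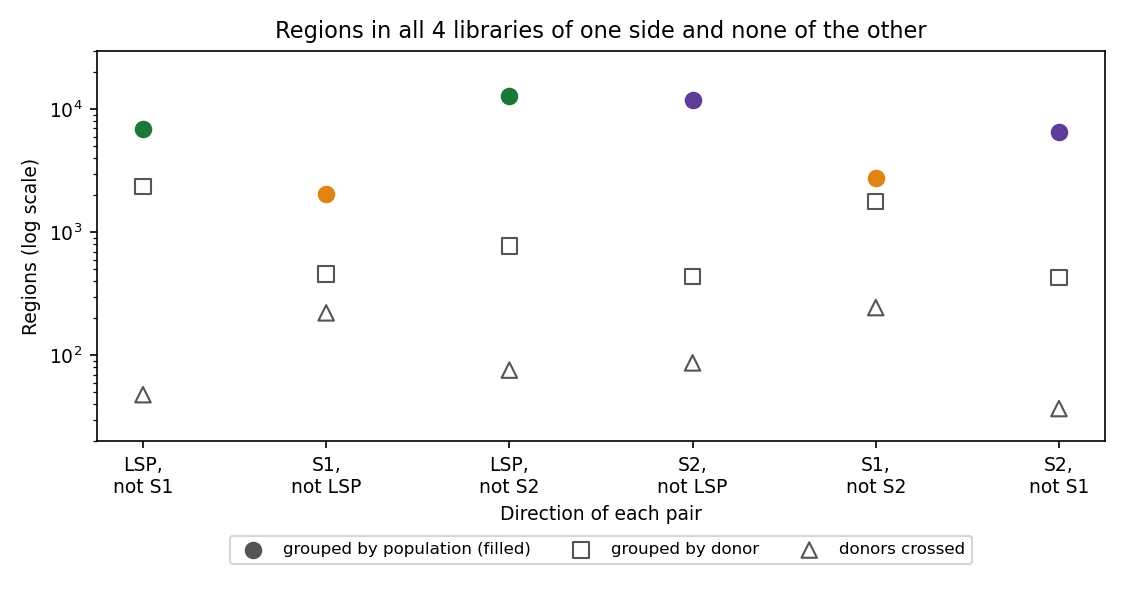
Number of regions (vertical log axis) present in all 4 libraries of one side and in none of the other, for both directions of each pair of populations (horizontal axis). Filled circles group the libraries by population, open squares by donor and open triangles with donors crossed. LSP and S2 give 12850 and 12023 regions, against 76 and 87 with donors crossed.

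LSP and S1 differed in fewer regions, and the differences were spread over many bands. There were 6931 regions specific to LSP and 2069 specific to S1, against 48 and 222 for crossed donors and 2352 and 459 for grouping by donor. Giemsa-negative bands held 60.7% of the LSP-specific and 48.2% of the S1-specific regions. They held 49.4% and 50.2% of the equal lists of S1 in donor 2. In 14q32.33 there were 12 regions specific to LSP and 0 specific to S1, in 5q33.3 there were 19 and 2, and in 9p13.2 there were 3 and 2. A summit of the other population lay within 100 bp at some rank for 64.6% of the LSP-specific and 79.2% of the S1-specific regions. The size of the imbalance differed between donors. In donor 1 alone, 16658 regions were specific to LSP and 14430 to S1, and in donor 2 alone 25962 and 7724. With S1 taken from donor 1 alone against both LSP donors the counts were 9399 and 11547, but 2 S1 libraries then had to share a region against 4 of LSP. With no summit of the other population within 1000 bp at any rank, 874 LSP-specific and 115 S1-specific regions remained. The counts were 0 and 0 for crossed donors and 59 and 11 for grouping by donor. The best-ranked of LSP lay at 88428992 of chromosome 6 (6q15) and 139641478 of chromosome 5 (5q31.3), and neither was found in any S2 or S4 library. The best-ranked of S1 lay at 48110317 of chromosome 8 (8q11.21), 83120013 of chromosome 6 (6q14.1) and 194117910 of chromosome 2 (2q32.3), and all 3 were also found in every S2 and S4 library. Limma called 0 of 12828 windows between LSP and S1, with 1425 at an unadjusted p under 0.05. The call count stayed at 0 with the donor as a block (2967 at an unadjusted p under 0.05) and was 137 when the libraries were fitted with an estimated correlation between technical replicates.

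In the EBF1 and IGH bands, more regions were specific to S2 than to S1. There were 2748 regions specific to S1 and 6579 specific to S2, against 245 and 37 for crossed donors and 1777 and 431 for grouping by donor. Of the S1-specific regions 47.2% lay in Giemsa-negative bands, against 61.8% of the S2-specific regions. The equal lists of S1 in donor 2 had 49.4% and 50.2% there. The S2-specific regions numbered 65 in 5q33.3 (4 specific to S1), 47 in 14q32.33 (3 specific to S1), 18 in 9p13.2 (1 specific to S1), 17 in 22q11.23 (0 specific to S1) and 11 in 22q11.22 (0 specific to S1). A summit of S1 lay within 100 bp at some rank for 60.9% of the S2-specific regions, and a summit of S2 for 69.1% of the S1-specific regions. In donor 1 alone the totals were 16095 for S1 and 16097 for S2, and in donor 2 alone 7985 and 23448. With S1 taken from donor 1 alone against both S2 donors they were 12664 and 8115, with 2 S1 libraries that had to share a region against 4 of S2. With no summit of the other population within 1000 bp at any rank, 381 and 1040 regions remained. The counts were 0 and 0 for crossed donors and 33 and 9 for grouping by donor. The best-ranked of S2 lay at 30383678 of chromosome 18 (18q12.1), 6948767 of chromosome 2 (2p25.2) and 53090986 of chromosome 18 (18q21.2). These were found in every S4 library and in no LSP library used. The best-ranked of S1 lay at 117517056 of chromosome 9 (9q32) and was found in every S4 library and every LSP library used.

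Without a block, limma called 0 windows between S1 and S2, with 1717 at an unadjusted p under 0.05, and with the donor as a block it called 524, of which 266 were higher in S1 and 258 in S2. Windows were named from the blocked fit by a rule chosen after the data were seen. The window in 6p25.1 on chromosome 6 from 5700001 to 5800000 held 3.25 ± 1.06 summits in S1 and 23.8 ± 0.35 in S2 (log2 difference S1 minus S2 of -2.56, SE 0.22, adjusted p = 0.0157 with the block and 0.151 without). The windows in 13q33.3 and 3p14.2 that start at 107300001 and 60200001 gave -2.99 and -2.88. Higher in S1 were windows in 8q21.11 (chromosome 8 from 77400001, 3.13), 3q22.2 (chromosome 3 from 134600001, 2.85) and 6q22.31 (chromosome 6 from 124200001, 2.81). Each of these 3 held 0 summits in S2 and S4. LSP held 5.75 ± 1.06, 2.42 ± 1.53 and 2.33 ± 0.47 summits in them (SD, n = 2 donors). Of the 524 windows, 204 were also called between LSP and S2 without a block, all in the same direction relative to S2.

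S1 held part of both the LSP-specific and the S2-specific landscape. In donor 1, S1 lists contained 34.6% of the 12850 LSP-specific and 36.9% of the 12023 S2-specific regions, and 96.5% of the 29874 regions found in both LSP and S2. In donor 2 the values were 26%, 20.4% and 82.4%. Of the 3293 LSP-specific and 2923 S2-specific regions with no summit of the other population within 1000 bp at any rank, S1 lists contained fewer: 17.6% and 14.8% in donor 1, and 18.9% and 9.56% in donor 2. The 95% Wilson intervals, which cover counting error only, ran from 34.26% to 35.91% for LSP-specific regions in technical replicate 1 of S1 in donor 1 and from 36.81% to 38.54% for S2-specific regions. In the 218 windows higher in LSP, S1 lay between the LSP and S2 means in 200 windows in donor 1 and 191 in donor 2. In the 271 windows higher in S2 it did so in 259 and 247. The median position of S1, with LSP at 0 and S2 at 1 on the log2 scale, was 0.37 in both donors for windows higher in LSP. It was 0.52 in donor 1 and 0.49 in donor 2 for windows higher in S2. In 14q32.33, the window on chromosome 14 from 106300001 to 106400000 differed from that order, with 4.5 ± 2.12 summits in LSP, 18.5 ± 0.71 in S1 and 15.8 ± 1.06 in S2 (adjusted p for LSP against S2 = 0.0442, and 0.0703 and 0.0720 without the S1 unit of donor 1 or donor 2). Windows chosen for a difference between LSP and S2 tend to place any other list between them, so these positions were not tested.

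**Figure D5:**
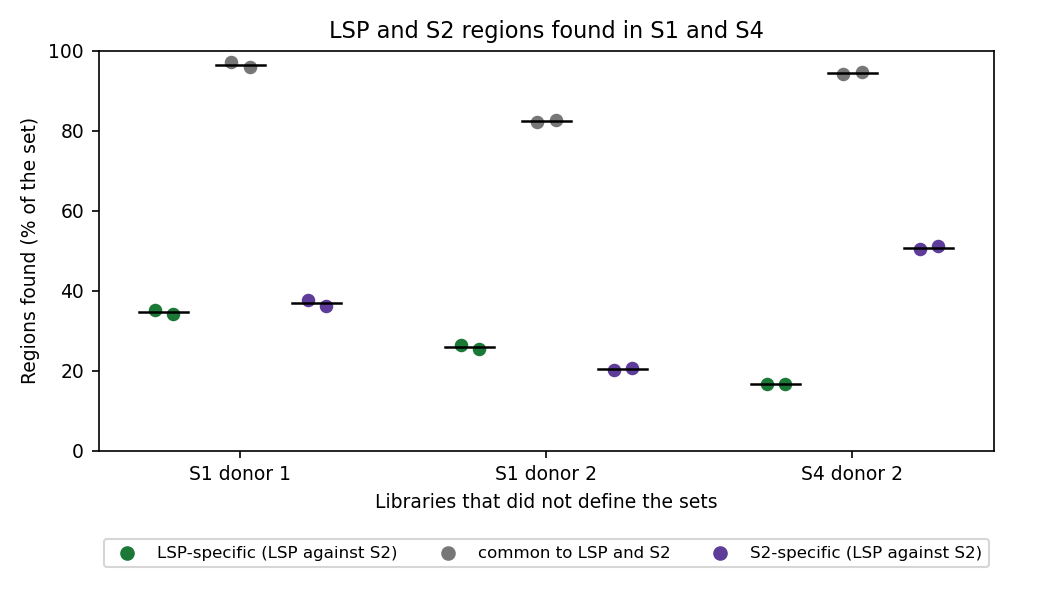
Percent of the LSP-specific regions, of the S2-specific regions (both from LSP against S2) and of the regions common to LSP and S2 (vertical axis) that were found in the S1 libraries of each donor and in the S4 libraries (horizontal axis). Points are technical replicates and lines their means. S4 holds 16.7% of the LSP-specific and 50.8% of the S2-specific regions.

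S4 was nearer to S2 than to LSP. S4 lists contained 50.8% of the S2-specific and 16.7% of the LSP-specific regions, and 94.4% of the regions common to both. Of the regions with no summit of the other population within 1000 bp at any rank, it held 41.1% and 5.91%. S4 came from 1 donor, so its differences have no replicate check and no test was made. Within donor 2, 17625 regions were specific to S4 and 14568 to S2, but 22662 and 25887 with all deposited summits, where the larger count is that of S2. Against LSP the counts were 25565 and 24960. Against S1 they were 30542 and 10041, with the S1 libraries of low score on the other side. The largest difference to S2 lay in 18q12.1, on chromosome 18 from 30400001 to 30500000, with 21 summits in S4 and 1 in S2. In 1q23.1 the window on chromosome 1 from 157500001 to 157600000 held 7 in S4 and 0 in S2. Windows with fewer summits in S4 included 1q42.13 (chromosome 1 from 228900001), with 0 summits in S4 and 9 in S2. Against LSP, the window in 3q25.2 on chromosome 3 in the 100 kb from 154800001, the band of MME (which encodes CD10, a surface marker of early B cells), held 14 and 17 summits in the S4 libraries and 0 in LSP, with 5.5 in S2 of the same donor. In 14q32.33 the window on chromosome 14 in the 100 kb from 106100001 held 10 and 17 summits in the S4 libraries, 0 in LSP and S1 and 1 in S2 of donor 2.

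Among the bands of the antigen receptor loci, those of the lambda and heavy chain loci had the highest ratios of S2 to LSP. Summits in 22q11.22 (IGL) were 2.07 ± 0.24 times as many in S2 as in LSP (SD, n = 2 donors), those in 14q32.33 (IGH) 1.69 ± 0.05 times and those in 2p11.2 (IGK) 1.13 ± 0.03 times. The ratio was 0.98 ± 0.01 in 7p14.1 (TRG), 1.00 ± 0.04 in 7q34 (TRB) and 0.94 ± 0.05 in 14q11.2 (TRA and TRD). Within donor 2, S4 held 161.5 summits in 22q11.22, S2 93, LSP 41.5 and S1, from its libraries of low score, 26. In donor 1, S2 held 144.5, S1 95 and LSP 76, so the order of S1 and LSP differed between donors. A band holds many other genes, and neither single bands nor differences between bands were tested. V(D)J recombination deletes DNA within these loci and can change what maps there.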

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

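All tests of explanations in this part were chosen after the results they bear on had been seen. In 15 combinations of population and measure (number of summits, scores, share in Giemsa-negative bands), no single library lay far from the others of its population; chance gives such a library in about 1 of 20 groups.

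In 5 cases every library of donor 1 moved one way and every library of donor 2 the opposite way, among 42 pairs of band and comparison; these differences between donors were not tested. LSP minus S2 in 1q32.2 was -16 summits in donor 1 and 11.5 in donor 2, a difference of -27.5. LSP minus S1 was -19 in donor 1 and positive in donor 2 in 22q11.22 (a difference of -34.5), -22.7 and 24 in 5q33.3 (-46.7) and -21.8 and 67 in 7q34 (-88.8). S1 minus S2 in 7q34 was 32 and -76.5 (108.5). The last 4 all involve the S1 libraries of donor 2. Outside the autosomes and sex chromosomes, 7976 summits lay on unplaced or alternate contigs, from 226 to 1023 per library, which no comparison used.

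The S1 libraries of donor 2 overlapped little with any list, each other included. A swap with LSP, S2 or S4 is argued against, within limits. The best 10000 summits of these libraries were found in S1 of donor 1 more often than in LSP, S2 or S4. The margin over the next population was 2.38 percentage points, and the technical replicates differed by less. S1 of donor 1 is 1 unit, so the margin was not set against the spread between donors. A swap of these libraries with samples outside the series could not be tested. Low enrichment of open chromatin is consistent with the overlap of their best 5000 summits, 96.5%, falling to 45.4% over the 100000, further than in any other pair. Enrichment itself was not measured, and whether fewer cells, fixation or depth played a part was not tested.

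LSP and S2 each had more specific regions against S1 than S1 had against them. Low enrichment of the S1 libraries of donor 2, if present, is a candidate explanation. LSP held 53.6% of the regions that differed from S1 in donor 1 alone and 77.1% in donor 2 alone. For S1 and S2, S1 held 50.0% in donor 1 and 25.4% in donor 2. A biological difference between the donors was not tested.

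For S1 between LSP and S2, lists of S1 that miss open regions of every kind alike are argued against in donor 1. There S1 held 96.5% of the regions common to LSP and S2. Those regions had to be in every LSP and S2 list used, so lists of S1 that miss weaker regions alone stay possible. A mix of LSP and S2 cells in the S1 gate, or an intermediate state of S1 cells, stays open: 18 regions were in every S1 library and in no deposited list of LSP or S2 (Poisson 95% interval 10.7 to 28.4), against 1736 private to LSP and 1986 private to S2 in the same count, and 264 in S1 of donor 1 alone, against 3036 for LSP and 3563 for S2 of donor 1. The highest crossed grouping gave 9 (exact binomial test of 18 against 9, p = 0.122). That test replaced a comparison of the interval with 9, which would have argued against the mix, after both counts had been seen, because the interval leaves out the error of the crossed count.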

How the results depend on the processing

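The windows named for their size or their band and called between LSP and S2, 45 in all, kept their sign in each alternative on 100 kb windows (24 of them with 50000 summits per library, where the others fell under the filter). All called windows had the same sign in both donors to begin with, so a kept sign adds little support. The 45 were not followed in 50 kb windows. With S1 from donor 1 alone, an alternative chosen after the data were seen, 9399 regions were specific to LSP and 11547 to S1, and 12664 to S1 and 8115 to S2; 2 S1 libraries then had to share a region against 4 of the other population, which by itself raises the S1 counts. The gene lists, the motif alternatives and the gene-based values of S4 were not run, for want of a matching annotation and genome. Depth is unknown, so what it limits could not be measured. The causes of the changes below were not tested. A rule that fewer libraries must meet can only raise a count of regions.

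Between LSP and S2, where 489 windows were called, the count was 172 with 50000 summits per library (90 of the 489 among them), 3 with all deposited summits, 0 with a score of at least 10, 808 in 50 kb windows, 0 without the filter on low windows and 1607 with libraries and an estimated correlation. Leaving out 1 donor unit gave 0 to 371 windows: 0 without either LSP or S2 unit, and 371 or 356 without an S1 unit. The lone unit left in a group is then assumed to vary like the others. The replicate block gave 2169 windows for LSP and S2 and 524 for S1 and S2 and left LSP and S1 at 0; no other call changed with it. Libraries with an estimated correlation gave 137 for LSP and S1 and 405 for S1 and S2. Of the 45, an adjusted p under 0.05 was kept by 45 with the block and without S4, 44 with libraries and an estimated correlation, 42 with a pseudocount of 0.5, 38 and 37 without the S1 unit of donor 1 or donor 2, 16 of 24 with 50000 summits, 3 with all deposited summits, and 0 without an LSP or S2 unit, with a score of at least 10 or without the filter on low windows.

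With 50000 summits per library, specific regions were 3454 (LSP against S1), 6628 (LSP against S2), 7625 (S2 against LSP), 4097 (S2 against S1), 9469 (S4 against S2) and 8976 (S2 against S4). With all deposited summits they were 11417 (LSP against S1), 21742 (LSP against S2, with 12318 for S2 against LSP) and 25887 (S2 against S4, with 22662 for S4 against S2, so that the larger count passes from S4 to S2). With a score of at least 10 they were 541 (S1 against LSP) and 972 (S1 against S2). With no other summit within 1000 bp they were 874 and 115 for LSP and S1, 3293 and 2923 for LSP and S2, and 381 and 1040 for S1 and S2. Leaving out a donor, or the S1 libraries of donor 2 alone, gave 9399 to 25962 (LSP against S1), 7724 to 14430 (S1 against LSP), 26035 to 27078 (LSP against S2), 24001 to 24656 (S2 against LSP), 7985 to 16095 (S1 against S2) and 8115 to 23448 (S2 against S1). Fewer libraries had to agree, which can only raise these counts. That does not account for the differences between donors, such as 16658 in donor 1 alone and 25962 in donor 2 alone for LSP against S1.

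With all deposited summits, overlap was 50.0% for technical replicates, 41.6% for donors of a population, and 37.4% and 38.0% for populations within and across donors. The last was 60.4% at 250 bp and 47.1% at 50 bp. The ratio of S2 to LSP with 50000 summits was 1.43 for the IGH band, 1.22 for IGK, 2.37 for IGL and 0.96 for TRG. With all deposited summits it was 1.07 for IGK, 1.77 for IGL, 0.84 for TRA and TRD, 0.91 for TRB and 0.88 for TRG.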

Other observations

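The tests of groupings in this part were set after the counts had been seen. Clusters of specific regions lay inside and outside the bands of the B-cell genes named above. The densest clusters of S2-specific regions against LSP lay in 6p25.1 (15 regions on chromosome 6 from 5700001 to 5800000) and 3q21.3 (13 on chromosome 3 from 128700001). Next were 5q33.3, the band of EBF1 (12 on chromosome 5 from 158100001), and 13q12.3 (12 on chromosome 13 from 30900001). The cluster in 6p25.1 was also the densest against S1, with 14 regions. The densest clusters specific to LSP lay in 2q13 (chromosome 2 from 113500001) and 10q22.3 (chromosome 10 from 81000001), with 11 regions each.

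Windows within a band of antigen receptor genes did not always move the same way, and none was assigned to a receptor locus. In 7q34, which holds the T-cell receptor beta locus, the band ratio of S2 to LSP was 1.00, yet 1 window was called in each direction. The window on chromosome 7 from 138800001 held 10.4 ± 0.12 summits in LSP and 2.25 ± 0.35 in S2. The window from 142000001 held 4.92 ± 0.59 in LSP, 11.5 ± 4.95 in S1 and 19 ± 0.71 in S2 (SD, n = 2), and 6.5 in S4. In 14q32.33 the window from 106700001 rose between LSP and S2 and held 5.5 summits in S4, while the window from 106100001 held 10 and 17 in the S4 libraries and 1 in S2 of donor 2.

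The region counts can be set beside the 3 groupings of the 4 donor units of each pair. The grouping by population gave the highest count for each pair, and was the 1 of 3 groupings to do so: 24873 regions for LSP and S2 (next 1213), 9000 for LSP and S1 (next 2811) and 9327 for S1 and S2 (next 2208). For windows, 489 were called between LSP and S2 and 0 in either other grouping. With 3 groupings a share under 0.05 cannot be reached.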
